A study of Homo sapiens with 12 samples.

How the data were processed

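The series profiled RNA bound by an antibody against 1-methylguanosine (m1G) in PANC-1 cells, an established line from a human pancreatic ductal adenocarcinoma. Polyadenylated RNA was fragmented and either immunoprecipitated with the antibody (IP) or kept as input, from control cells and from cells depleted of TRMT5 with siRNA for 4 days. Per the labels, 12 libraries form 4 groups of 3: input control, m1G IP control, input TRMT5 knockdown and m1G IP TRMT5 knockdown, all of experiment 2. The labels do not say whether replicates came from separate cultures.

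The 2 files used here are peak lists of the whole series, so no value belongs to a single library, and the read depth of the libraries is unknown. Per the submitters' processing notes, the tools included STAR 2.7.1, SAMtools, Picard, bedtools, MACS2 2.2.5, featureCounts, edgeR, DESeq2 and ChIPseeker with the GRCh38 genome. The notes as used here give no role or order for these tools. Which libraries entered the peak calling, whether replicates were pooled and which settings were used are not given in the sources used here. The lists have no header, and each unit was read from the layout and the values. The deposited MACS2 list gives positions of 1 base (summits) with a −log10 value. This was taken as −log10 of a q-value because its smallest value, 1.35, lies just above −log10 of 0.05. The names of the summits contain a length of 300 bases whose meaning is not given in the sources used here. The second list carries the name MetDiff and gives an Ensembl gene ID, a strand and exon blocks for each peak. The deposited MetDiff values are a p-value, its log10, the log10 of a false discovery rate (FDR) and a ratio. The ratio was taken as the fold enrichment of IP over input from the place of that column in the layout of such tables, which no header states. It was under 1 in 0 of the peaks. That reading was not settled from the data, and a ratio of another contrast is not excluded. The log10 of the p-value column differed from the log10 column by at most 0.02. All fold, FDR and −log10 q values printed for peaks are the authors'. They were used to describe, rank or filter peaks within their own list. The fold also entered comparisons between groups of genes or peaks and a rank correlation with −log10 q across the lists.

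Coordinates are GRCh38, counted from 1. As a check of the build, 99.8% of MetDiff peaks overlapped a gene span of the RefSeq table used here (GRCh38), against 66.6% after all peaks were moved by 1000000 bases. The table holds gene spans without exons, strand or matched Ensembl IDs, so genes were named by position. A MetDiff gene ID was named when exactly 1 RefSeq gene of any biotype spanned all its peaks, which held for 3872 of 4515 IDs (85.8%), with 583 IDs in several genes and 60 in none. Of the named IDs, 256 shared their gene name with another ID. A name by position thus need not be that of the Ensembl gene. A summit was named when it lay in exactly 1 gene, which held for 3129 of 3705 summits (84.5%). No genome sequence or exon annotation was used here. Positions in untranslated or coding regions and the guanine content of peaks, both planned, were therefore not analysed here. The planned comparison of knockdown with control was not made, because no column of either list is labelled as such a value.

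Genes named in the text follow a rule set before the data were examined: TRMT5 and NES; the 15 genes with the highest fold or −log10 q in each list, among peaks with a sole gene; the 10 genes with the highest −log10 q among summits that lie inside a MetDiff peak; and, of each gene list that passed its test, the 4 members with the strongest peak. Other genes named, among them the non-coding RNAs outside the gene lists and the paralogs of HNRNPK, were chosen after their values were seen. In the same way 29 gene lists were fixed, 28 of them with protein-coding members. The result of 1 of these lists is counted in the totals but not reported here. For these, members with a peak were compared with all other protein-coding genes of the RefSeq table (20050 in all) by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the 28 lists of each peak list and a threshold of 0.05. No expression table was used here, so genes that the cells do not express are in this background. Median fold of the members with a peak was set against the median of all genes with a peak, members included, by a 2-sided permutation test with 100000 random draws of as many genes, for the 22 lists with at least 5 such genes. Shares have 95% Wilson intervals, which cover counting error only.

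Overlap of the lists was counted when a summit lay inside an exon block. It was set beside 1000 random placements of the summits, within 2000 bases of each summit or within the span of its gene. The planned placement within exons was not run, and no p-value is given for these placements because they reach into introns. The distance of each summit from the midpoint of the nearest block within 150 bases was measured in genomic bases, without removal of introns. Its sign was set by the strand, with negative values towards the 5′ end. On simulated data of 20050 genes, 97% of lists set to a share of 60% against 18% elsewhere were recovered and 0% of unchanged lists were called. All genes outside the raised lists had the same simulated chance of a peak. Unexpressed genes in the background were not simulated, so the 0% does not cover calls that arise from them. A simulated displacement of −100 bases over 1000 positions was recovered as −100 bases. Alternatives were stricter thresholds (FDR or q under 0.01), a fold of at least 2, other naming rules, other backgrounds, gene span as a covariate, and other definitions of overlap. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.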

Results

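Sites bound by an anti-m1G antibody were listed for polyadenylated RNA of PANC-1 pancreatic cancer cells, as control cells and as cells depleted of TRMT5, the methyltransferase that makes m1G next to the anticodon of tRNAs. The question of the experiment was which mRNAs may carry m1G. The 12 libraries formed 4 groups of 3 (input and m1G IP, control and TRMT5 knockdown). The values below come from 2 peak lists of the whole series, which hold no value per library and no column named as knockdown against control, so no difference between the groups was tested. The fold of the MetDiff list was read as IP over input from its place in an unlabelled layout. If it were a contrast of another kind, such as one between knockdown and control, every fold below would have another meaning. The depth of the libraries is unknown.

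The MetDiff list held 9585 peaks under 4515 gene IDs, with a median of 2 peaks and a maximum of 14 per ID. Their fold enrichment ranged from 1.0 to 61.5 with a median of 4.5, and they covered between 92 and 741 exonic bases with a median of 101. The MACS2 list held 3705 summits, with −log10 q between 1.35 and 241 and a median of 13.7. Of 20050 protein-coding genes, 3678 were the sole gene at a MetDiff peak (18.3%, 95% Wilson interval 17.8 to 18.9) and 1655 the sole gene at a summit (8.25%, 7.88 to 8.64). Both lists shared 1383 of these genes, against 304 for independent lists of these sizes (Fisher's exact test, odds ratio 35.7, p below the floor of 1e-300 at which it was recorded). The same libraries may underlie both lists, so the overlap is not independent evidence. The value of 304 counts all 20050 protein-coding genes, also those that the cells do not express. Independent lists drawn only from expressed genes would share more. All these counts leave out peaks in several gene spans. With peaks named by a sole protein-coding gene, 3893 genes had a MetDiff peak and 1753 a summit. The intervals do not cover this choice of rule.

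TRMT5, the depleted gene, and NES, which encodes the intermediate filament protein nestin, both had MetDiff peaks. TRMT5 (chromosome 14, 60971441 to 60981690, minus strand) had 3 peaks, from 60975116 to 60975794, from 60975893 to 60979468 and from 60979567 to 60979865, with folds of 17.8, 11.8 and 7.11 and an FDR of 2.45e-06 in each. Together they covered 1295 exonic bases, and 56 of the 3744 genes named in the list (1.5%) had at least as many. Its median fold of 11.8 was reached by 238 of those genes (6.36%). TRMT5 had 0 summits in the MACS2 list. It was the target of the siRNA, and the libraries that entered the peak calling are not known. Whether the knockdown itself shaped the values of its peaks therefore cannot be told.

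NES (chromosome 1, 156668763 to 156677407, minus strand) had 8 MetDiff peaks and 7 summits. The peak with the highest fold, 15.1 (FDR 3.80e-05), lay at 156669161 to 156669459 near the 3′ end of the span, and the next, 8.19 (FDR 2.04e-04), at 156675322 to 156676860 near the 5′ end. The other NES peaks had folds between 2.80 and 6.05. They covered 1698 exonic bases in all, a length reached by 19 genes (0.507%), while the median fold of 4.69 was close to the middle of the list (reached by 50.6% of genes). The strongest NES summit, with −log10 q of 40.0, lay at position 156669531, and the weakest, with 4.01, at 156672989. The study chose TRMT5 and NES, so their peaks are not an independent test, and as a list of 2 genes they did not pass the threshold (Fisher's exact test, adjusted p = 0.0520 in the MetDiff list). With peaks at FDR under 0.01 the adjusted p was 0.0477.

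**Figure D1:**
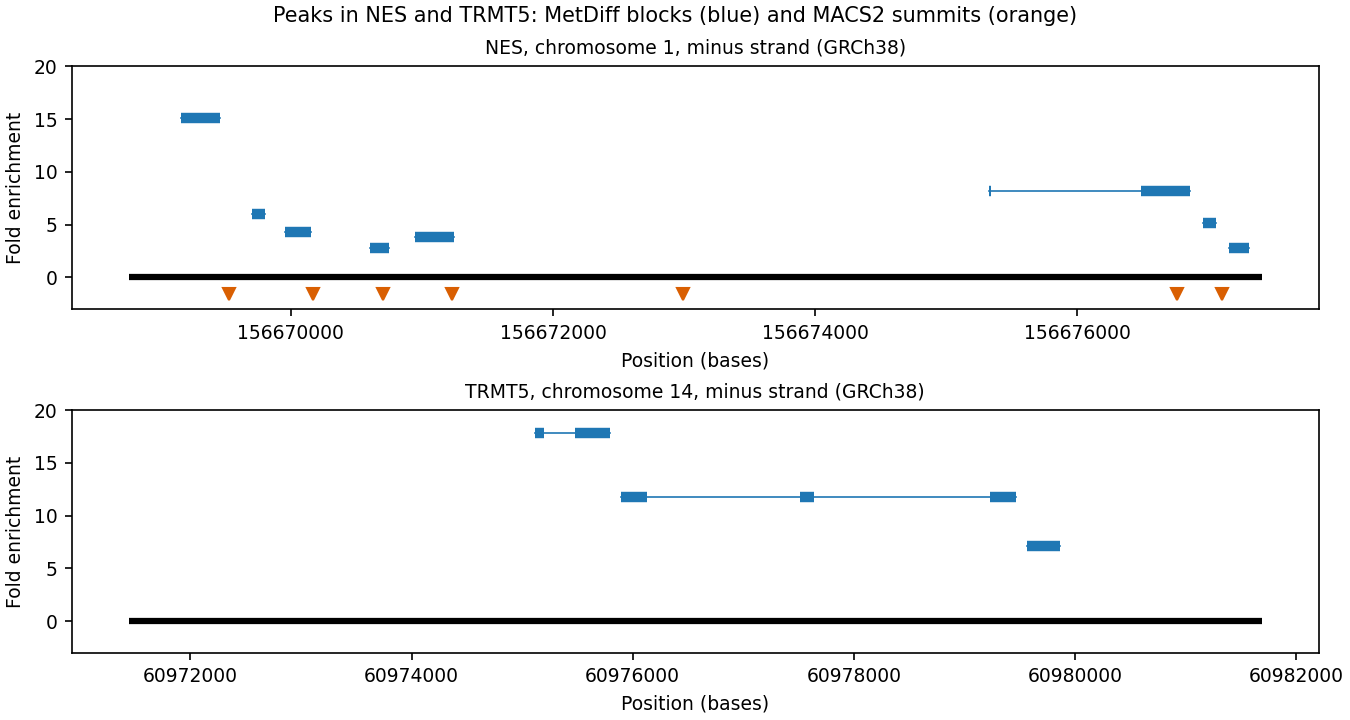
Maps of NES and TRMT5 with position in bases on the x axis and the authors' fold enrichment on the y axis; blue bars are exon blocks of MetDiff peaks (thin lines join the blocks of a peak), orange triangles are MACS2 summits and black lines the gene spans. NES had 8 peaks and 7 summits, TRMT5 3 peaks and 0 summits.

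By fold, the MetDiff list was led by a peak in the pseudogene HNRNPKP1 (chromosome 5, 127511710 to 127511809) with a fold of 61.5 and an FDR of 3.98e-08. The parent gene HNRNPK, which encodes an RNA-binding protein, had a fold of 30.6 (chromosome 9, 83970735 to 83970962) and the pseudogene HNRNPKP4 one of 33.8. Reads can be shared between these near-identical copies, so the assignment of all 3 peaks is uncertain. Among protein-coding genes, FSCN1, which encodes the actin-bundling protein fascin, had the highest fold, 52.3 (chromosome 7, 5592816 to 5592916, FDR 2.57e-07). The secreted protease HTRA1 followed with 50.7 (chromosome 10, 122461744 to 122461844), the metalloprotease ADAM33 with 49.7 and the Janus kinase TYK2 with 48.5 (chromosome 19, 10380423 to 10380522). GAREM2 had a fold of 48.3, the mitochondrial dynamics protein MIEF2 48.1, the adenylyl cyclase ADCY3 44.0, TMEM276-ZFTRAF1 43.8, the polarity protein SCRIB 43.5 and the growth factor HDGF 41.6. The asparaginyl-tRNA synthetase NARS1 and LOC124904704 both had 40.7, APLP1 had 40.3 and the epoxide hydrolase EPHX1 40.2.

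The MACS2 list was led by other genes. Its −log10 q is a measure of significance and not of fold, so the ranking by it is not one of enrichment. The ranking holds genes that were the sole gene at a summit; 7 summits in several gene spans or in none lay above the last gene named, and 2 such MetDiff peaks lay above the last gene named by fold. H19 (107) and MALAT1 (92.0) are absent from the ranking for this reason. The strongest named summit lay in RNA45SN1, a copy of the ribosomal RNA precursor gene, with −log10 q of 146, followed by HFM1, a meiotic DNA helicase gene, with 142 (chromosome 1, 91387541). Reads can be shared between copies of the precursor gene, so the assignment to RNA45SN1 is uncertain. The HFM1 summit lay outside all MetDiff exon blocks. Gene spans include introns, so this summit need not lie in an exon of HFM1. Whether its reads came from HFM1 mRNA was not tested. The glycolytic enzyme PKM had 141 (chromosome 15, 72208931), VWA1 131, ACTB, which encodes beta-actin, 127, and the actin-severing protein CFL1 124. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 had 121 and 96.4. GSN, another actin-severing protein, had 100.07, LOC112268204 99.0, the apolipoprotein APOE 97.7, ACTG1, which encodes gamma-actin, 97.3, PLEKHG2 94.5, MT-CO1 94.0 and the lysosomal protein PSAP 91.3. The 10 genes with the strongest summits inside a MetDiff peak were PKM (fold 7.59), VWA1 (5.81), CFL1 (4.52), MT-RNR1 (1.27), PLEKHG2 (12.2), the glycolytic enzyme TPI1 (10.2), the collagen COL18A1 (5.06), TRIR (9.15), the initiation factor subunit EIF3A (10.7) and the integrin ITGB5 (6.18). Across 2209 MetDiff peaks paired with their strongest summit within 150 bases, fold and −log10 q had a Spearman rho of 0.0878, across peaks that are not independent replicates.

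Genes of the cytoskeleton, glycolysis, splicing, the secretory pathway and translation had peaks more often than other protein-coding genes in both lists. Of 28 gene lists, 15 passed the threshold with more peaks in the MetDiff list and 15 in the MACS2 list, 13 of them in both (Fisher's exact test, Benjamini-Hochberg adjusted). The background includes genes that are not expressed in these cells. The list of cytoskeletal and intermediate filament genes had 22 of 30 members with a MetDiff peak (73.3%, 55.6 to 85.8, adjusted p = 2.11e-09) and 22 of 30 with a summit (adjusted p = 5.53e-17). In it, the filamin FLNA had a fold of 18.9, the spectrin SPTBN1 14.4, the tropomyosin TPM3 10.2 and the cytolinker PLEC 9.80, and the myosin MYH9 had a summit with −log10 q of 71.0. Among the 18 genes of glycolysis, 12 had a MetDiff peak (adjusted p = 4.92e-05) and 12 a summit (adjusted p = 5.21e-09). PFKL and PFKM, which encode subunits of phosphofructokinase, had folds of 15.3 and 14.5, and GPI had 8.0. ENO1 and GAPDH had summits with −log10 q of 52.3 and 50.9.

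Of the 31 splicing factors and hnRNPs, 20 had a MetDiff peak (64.5%, adjusted p = 2.60e-07) and 20 a summit (adjusted p = 6.30e-14). SF3B2 had a fold of 14.9, SRRM2 9.08 and SRSF6 8.67, and the strongest summits were in HNRNPU (49.0) and U2AF2 (43.6). Among 22 genes of ER chaperones and the secretory pathway, 15 had a MetDiff peak (adjusted p = 3.75e-06) and 12 a summit (adjusted p = 1.14e-07). The ER chaperones HYOU1, CANX and HSP90B1 had folds of 12.5, 12.2 and 10.4, and CALR and PDIA3 had summits of 69.8 and 60.7. Of 22 heat shock and folding genes, 11 had a MetDiff peak (adjusted p = 0.00231) and 11 a summit (adjusted p = 1.23e-06). The chaperonin subunit TCP1 had a fold of 30.8 and HSPH1 14.9, while HSP90AB1 had the strongest summit of that list (75.3). Of 25 adhesion and matrix genes, 13 had a MetDiff peak (adjusted p = 5.92e-04) and 11 a summit (adjusted p = 5.48e-06). The laminin LAMA5 had a fold of 18.4, agrin (AGRN) 18.3, perlecan (HSPG2) 16.2 and LAMC1 12.9.

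Genes of translation had peaks at several levels of the machinery. Of 78 cytosolic ribosomal protein genes, 27 had a MetDiff peak (34.6%, adjusted p = 0.00208) and 38 a summit (48.7%, adjusted p = 1.29e-19). RPS20 had the highest fold of these, 13.8, followed by RPS9 with 11.8, and RPL3 had the strongest summit (77.9). Of 30 translation factors, 12 had a MetDiff peak (adjusted p = 0.0129) and 16 a summit (adjusted p = 1.15e-09). EIF3B had a fold of 14.7 and the release factor ETF1 14.1, and EIF3A and the elongation factor EEF2 had summits of 76.6 and 65.0. Of 20 cytosolic aminoacyl-tRNA synthetases, 12 had a MetDiff peak (60%, adjusted p = 1.93e-04) and 8 a summit (adjusted p = 2.75e-04). Besides NARS1, HARS1 and VARS1 both had a fold of 15.6 and CARS1 had 6.68. With genes that had a MetDiff peak as the background, the summits of the synthetases no longer passed (Fisher's exact test, adjusted p = 0.339).

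Among the other lists, 16 of 25 chromatin regulators had a MetDiff peak (adjusted p = 4.21e-06) and 6 a summit (adjusted p = 0.0283), with folds of 14.3 in the bromodomain gene BRD2 and 13.1 in the methyltransferase gene KMT2B. Of 30 epithelial-mesenchymal transition genes, 13 had a MetDiff peak (adjusted p = 0.00383) and 10 a summit (adjusted p = 2.58e-04), with folds of 15.5 in the collagen COL6A1 and 12.6 in N-cadherin (CDH2). Of 20 integrated stress response genes, 9 had a MetDiff peak (adjusted p = 0.0119) and 5 a summit (adjusted p = 0.0386), with a fold of 11.9 in PPP1R15A and 10.1 in SHMT2. Of 16 YAP and TEAD targets, 7 had a MetDiff peak (adjusted p = 0.0296) and 5 a summit (adjusted p = 0.0166), with a fold of 11.9 in CRIM1. With MetDiff genes as the background, the summits of these 4 lists no longer passed (Fisher's exact test, adjusted p between 0.226 and 0.917), and the difference of the chromatin regulators changed sign. Genes of mitosis passed in the MetDiff list (12 of 30, adjusted p = 0.0129 by Fisher's exact test), with a fold of 7.84 in PRC1, and not in the MACS2 list (5 of 30, adjusted p = 0.169). Whether their share differs between the peak lists was not tested. The mitochondrially encoded mRNAs passed in the MACS2 list (11 of 13, adjusted p = 5.49e-10 by Fisher's exact test), and 0 of 13 had a MetDiff peak. Of 33 nuclear genes of oxidative phosphorylation, 9 had a summit (adjusted p = 0.00253 by Fisher's exact test) and 10 had a MetDiff peak (30.3%, adjusted p = 0.140), so their number was not higher in the MACS2 list. CYC1 had the strongest summit among them (30.1), and with MetDiff genes as the background the adjusted p of their summits was 0.367.

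Fewer peaks than in other genes were found for the replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, with 0 of 33 (adjusted p = 0.00611), and for KRAB zinc finger genes, with 0 of 30 (adjusted p = 0.00850), in the MetDiff list. In the MACS2 list, 0 of the 28 lists passed with fewer peaks; these groups had summits in 0 of 33 and 1 of 30 members (adjusted p = 0.179 and 0.596 by Fisher's exact test). Markers of immune cells (0 of 13) and of acinar, islet and stellate cells (0 of 19) had no peak in either list, which did not pass the threshold (adjusted p = 0.169 and 0.0520 in the MetDiff list by Fisher's exact test). tRNA modification enzymes had MetDiff peaks in 11 of 35 members, with a fold of 14.9 in TRMT61A, and summits in 5 (adjusted p = 0.106 and 0.305 by Fisher's exact test). The mRNA modification machinery had MetDiff peaks in 5 of 22 members, with a fold of 14.1 in METTL3, and a summit in 1. Mitochondrial ribosomal proteins (8 of 30 with a MetDiff peak and 4 with a summit), DNA replication genes (9 of 30 and 4), p53 targets and apoptosis genes (5 of 20 and 2) and pancreatic cancer genes (6 of 24 and 1) did not pass in either list. Median fold of the members with a peak differed from that of random draws of as many genes with a peak in 0 of 22 lists, and 0 had an unadjusted p under 0.05 (permutation test). The lowest p was that of the integrated stress response genes, with a median fold of 3.17 against 4.71 over all genes with a peak, members included (permutation test, p = 0.0541, 9 genes).

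**Figure D2:**
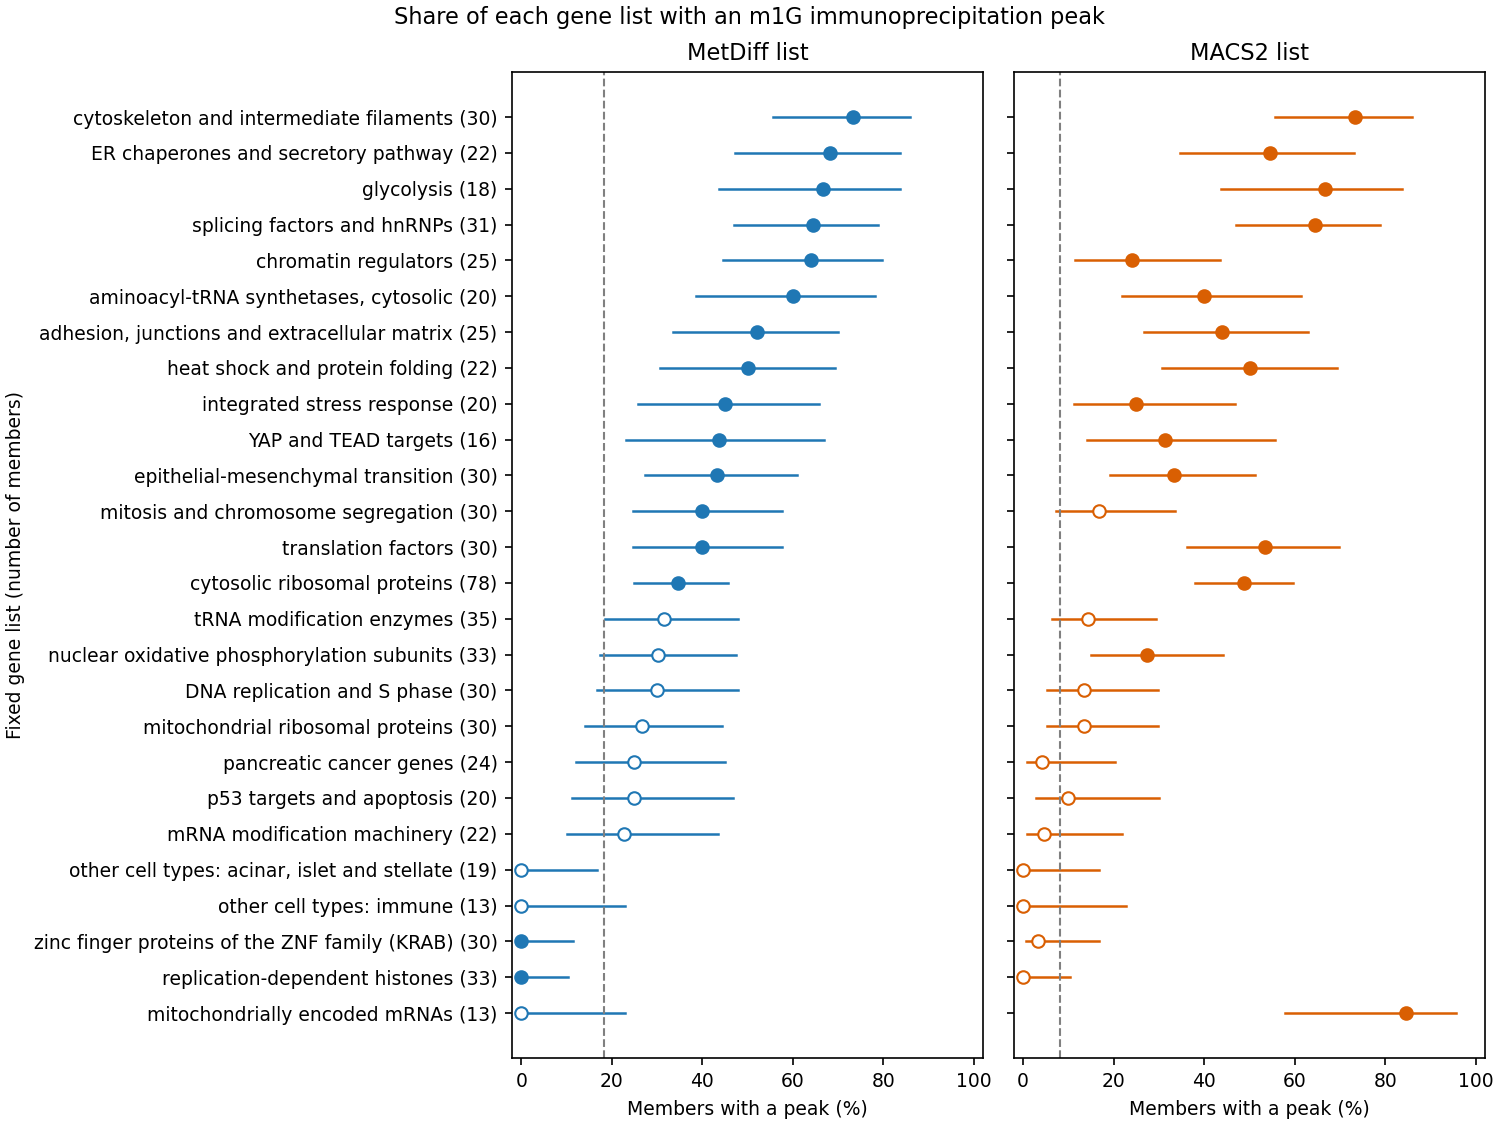
Percent of the protein-coding members of 26 gene lists (y axis, number of members in brackets; 2 of the lists tested, TRMT5 and NES among them, are left out) with a MetDiff peak (left) or a MACS2 summit (right). Bars are 95% Wilson intervals, dashed lines the share in other protein-coding genes, and filled points passed the adjusted threshold of 0.05; the cytoskeletal list had 73.3% in both, and the mitochondrially encoded mRNAs 84.6% in the MACS2 list and 0% in the MetDiff list.

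Several non-coding RNAs had peaks. Of 14 long non-coding RNAs on the list fixed before the data were examined, 3 had a MetDiff peak (NEAT1, NORAD and TUG1) and 2 a summit (NEAT1 and NORAD) as the sole gene at the peak, the rule used for all other lists. Counting any peak inside the span, also where another gene overlaps it, gave 5 and 4, with H19 and MALAT1 in addition. H19, an imprinted RNA, had 4 MetDiff peaks with folds up to 11.3 and 5 summits with −log10 q up to 107. NEAT1, the RNA scaffold of paraspeckles, had 10 MetDiff peaks with folds up to 12.7 and 5 summits up to 34.6, and MALAT1 had 1 MetDiff peak with a fold of 3.75 and 8 summits up to 92.0. On the mitochondrial genome lay 23 summits and 2 MetDiff peaks, the latter both in MT-RNR1 with folds of 1.27 and 1.47. The strongest summits in mitochondrial mRNAs were those of MT-CO1 (94.0 at position 6318), MT-CO2 (76.8), MT-ND1 (53.01) and MT-ND4 (49.2).

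tRNAs are the known substrates of TRMT5. No MetDiff peak or summit overlapped any of the 443 nuclear tRNA genes or the 22 mitochondrial tRNA genes of the RefSeq table. Within 150 bases there were 0 of either at nuclear tRNA genes, and 2 MetDiff peaks, both in MT-RNR1, and 4 summits at mitochondrial ones. MetDiff peaks were placed in exons of genes with an Ensembl ID. Whether that gene set held tRNA genes is not known, so the absence from this list may have been fixed in advance. The libraries were made from polyadenylated RNA, and reads from tRNAs were not analysed here.

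The 2 lists placed their peaks at neighbouring but mostly not identical positions. Of 3705 summits, 655 lay inside a MetDiff exon block (17.7%, 16.5 to 18.9). After moving each summit by a random distance of up to 2000 bases, a mean of 196 of the 3705 (5.30%) lay inside a block over 1000 placements. Within the whole span of genes with a MetDiff peak, random placement gave a mean of 101 of 2728 (3.70%), where 570 were observed (20.9%). Both placements reach into introns while the blocks are exonic, which lowers the random values in advance, so they give no test of shared positions within exons. Within 150 bases of a block lay 2358 summits (63.6%), a distance chosen after seeing the data. Of these, 87.1% were on the 5′ side of the block midpoint, with a median distance of −106 bases (quartiles −131 and −62.5). The median was −105 bases in genes on the plus strand and −106 in genes on the minus strand. Moving every block 100 bases towards the 5′ end of its transcript, a distance chosen after that median was seen, raised the share of summits inside a block to 49.3% (47.7 to 50.9), and moving it 100 bases towards the 3′ end gave 7.15%. In PKM, for example, the summit at 72208931 lay inside the peak from 72208760 to 72208959 on its 5′ side, on the minus strand. MetDiff peaks with a summit within 150 bases had a median fold of 6.02, and the others one of 4.16.

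**Figure D3:**
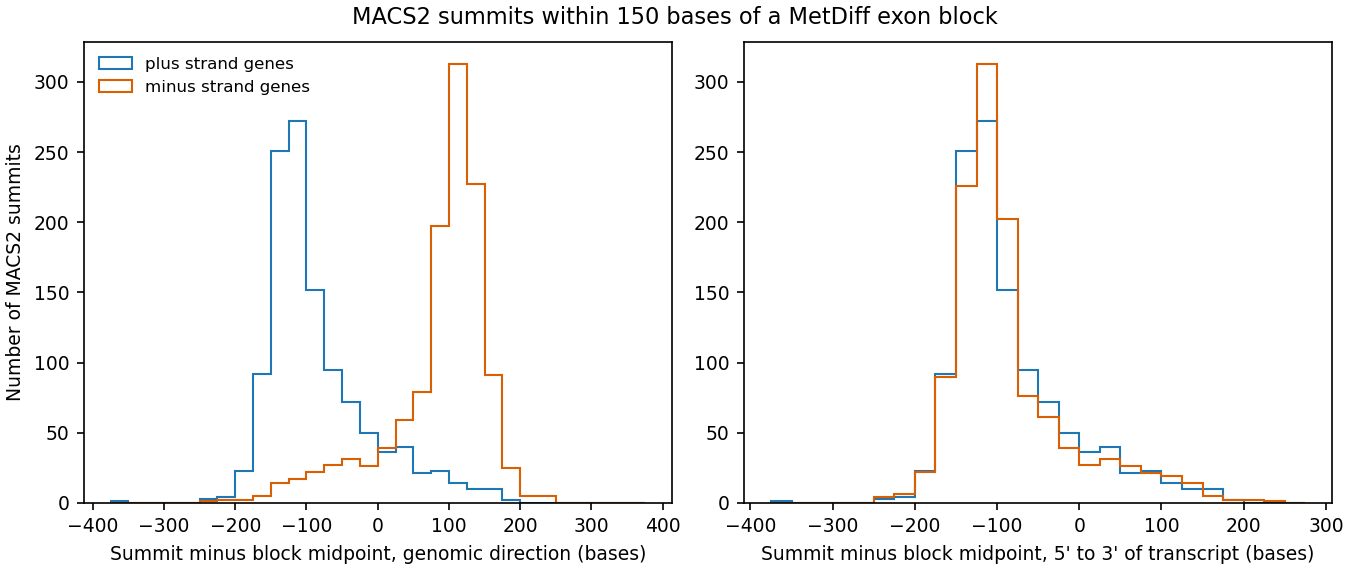
Histograms of the distance in bases from the midpoint of the nearest MetDiff block to each MACS2 summit within 150 bases of a block, in genomic direction (left) and from 5′ to 3′ of the transcript (right), for genes on the plus (blue) and minus (orange) strand; the y axis counts summits. In genomic direction the medians were −105 and 106 bases, and in transcript direction −105 and −106 bases, both counted in genomic bases.

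Along the genomic span of their genes, 8522 MetDiff peaks were most frequent at both ends. The 10% of the span at the 5′ end held 18.97% of them (18.2 to 19.8) and the 10% at the 3′ end 25.4% (24.5 to 26.3). In genes with a span of at most 10000 bases, the 3′ end held 11.9%. Spans include introns, and positions in untranslated or coding regions were not analysed here.

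Genes of chromosomes 22, 16, 17 and 19 had peaks most often. On chromosome 22, 139 of 451 protein-coding genes had a MetDiff peak (30.8%, 26.7 to 35.2; Fisher's exact test against all other genes, adjusted p = 8.02e-10). The share was 26.9% on chromosomes 16 (adjusted p = 1.69e-09) and 17 (adjusted p = 3.43e-12) and 25.5% on chromosome 19 (adjusted p = 2.52e-11). It was lowest among the nuclear autosomes on chromosome 13 with 8.58% (6.04 to 12.1, adjusted p = 1.98e-06 by Fisher's exact test) and chromosome 4 with 10.9% (adjusted p = 5.18e-08). Summits were found in 15.3% of the genes of chromosome 22 and 2.96% of those of chromosome 13. Across the 22 autosomes and chromosome X, the share with a MetDiff peak fell with the log10 of the median gene span (Pearson's r = −0.59, permutation p = 0.00303; Spearman's rho = −0.57, permutation p = 0.00505), and without the 2 chromosomes farthest from the median span r was −0.54 (permutation p = 0.0122). The relation rests on that choice of chromosomes: with chromosome Y and the mitochondrial genome included, r was 0.43 (permutation p = 0.0362) and rho −0.22 (permutation p = 0.285). Across single genes the shortest of 4 strata of gene span had the lowest share with a MetDiff peak. On chromosomes 16, 17, 19 and 22 it was 19.9%, against 27.2% to 33.6% in the longer strata. Elsewhere it was 10.8%, against 16.3% to 19.3%. The relation across chromosomes thus does not show that genes with the shortest spans had peaks more often. These comparisons were chosen after seeing the data, and the p-values of the correlations are not adjusted.

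**Figure D4:**
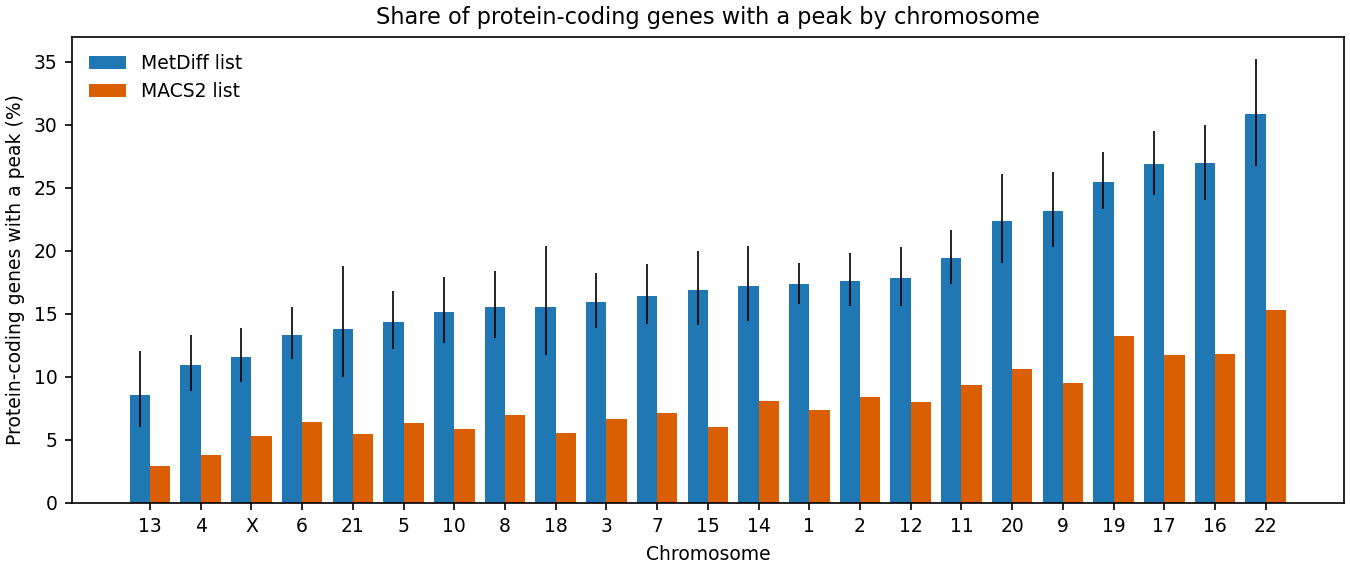
Percent of protein-coding genes with a MetDiff peak (blue, with 95% Wilson intervals) or a MACS2 summit (orange) on each of the 22 autosomes and chromosome X, in order of the MetDiff share; chromosome Y and the mitochondrial genome are not plotted. Among those plotted, the share rose from 8.58% on chromosome 13 to 30.8% on chromosome 22.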

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

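Overlap within 150 bases or with moved blocks, the naming rule by sole protein-coding gene, the chromosomes compared, the stratification by gene span and the settings for positions along gene spans were chosen after the data were seen; the other settings were planned. Of 32 summary values recomputed, 26 stayed within their interval or within 1.5 times the count. The share of summits inside a MetDiff block was 63.6% within 150 bases and 49.3% after the blocks were moved 100 bases to the 5′ end, both by construction wider or displaced. The number of gene lists with more summits than the background was 8 with MetDiff genes as the background, where fewer genes are tested. The share of peaks in the 3′ 10% of the span was 11.9% in genes of at most 10000 bases; the cause was not tested. With chromosome Y and the mitochondrial genome included, Pearson's r of chromosome share and gene span reversed to 0.43 and Spearman's rho was −0.22, no longer past the threshold; both additions have shorter median spans than any other chromosome. Among single gene lists, 175 values kept their direction and side of the threshold, 5 kept only the direction, 1 passed in addition (TRMT5 and NES at FDR under 0.01) and 1 reversed: the log2 odds ratio of chromatin regulators among summits was −0.34 with MetDiff genes as the background (Fisher's exact test, adjusted p = 0.917), and the cause was not tested. An overlap of most of the shorter peak, as planned, equals the main definition for summits of 1 base, and a limit of 1000 exonic bases removes no peak. With gene span as a covariate, lists with 0 members with a peak could not be fitted. No paired analysis was possible because the lists hold no value per library, and for the same reason no replicate was left out. Peak location in transcripts, base composition, placement within exons and knockdown against control were not run.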

Other observations

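The tests of explanations in this part were chosen after the result was seen. The count of gene lists that passed and the shares of single lists repeated here come from the planned tests. Some RNAs transcribed by RNA polymerase III and a small nucleolar RNA, not part of any list, also had summits: the signal recognition particle RNAs RN7SL3 (−log10 q of 79.1), RN7SL1 (77.8) and RN7SL2 (15.02), the RNase P RNA RPPH1 (57.6), the RNase MRP RNA RMRP (49.8) and the small nucleolar RNA SNORD3A (20.1). MetDiff folds of these were low where present, at 3.39 in RPPH1, 3.04 in RN7SL2 and 2.03 in SNORD3A. Whether reads were shared between the RN7SL genes was not analysed, so the assignment among them is uncertain. RN7SK and SCARNA2 had 0 summits and 0 MetDiff peaks. Nuclear ribosomal RNA genes (biotype rRNA) held 15 summits, with −log10 q from 7.04 to 175. The strongest summit of the MACS2 list, with −log10 q of 241, lay in no gene span (chromosome 3, position 93470577), as did the next of that kind with 130 (chromosome 3, position 186570706). MRPL13, of a list that did not pass, had a MetDiff fold of 38.4 and 0 summits. TRMT1, another tRNA methyltransferase, had 3 MetDiff peaks with a fold up to 9.69 and 9 summits with −log10 q up to 21.2, whereas TRMT5 had 3 MetDiff peaks and 0 summits.

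The MACS2 summits lay on the 5′ side of the MetDiff blocks. Blocks too coarse to place a summit, with no direction, would put about as many summits on either side, but 87.1% (85.7 to 88.4) were on the 5′ side, which argues against that explanation. A fixed displacement of positions in transcript direction between the callers may account for the pattern. It needs like medians on both strands, and these were −105 bases on the plus and −106 on the minus strand, a difference of 1 base. Any other cause that runs along the transcript would also give like medians, so this check cannot tell them apart. The distances were also spread, with quartiles of −131 and −62.5 bases. Which of the lists is displaced, or whether both are, stays open, since the settings of the callers and the handling of fragments are not given in the sources used here. No biological explanation was tested.

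Of the fixed gene lists, 15 held more MetDiff peaks than other genes. A limit from read depth, by which a peak can be called only in transcripts with enough reads, could contribute and stays open, since expression was not analysed here; the order of the lists (64.0% of chromatin regulators, 34.6% of cytosolic ribosomal proteins, 0% of mitochondrially encoded mRNAs) was not tested against abundance. Stronger enrichment in these lists was not seen: the 210 members of lists that passed had a median fold of 4.43 against 4.74 in other genes, a log2 difference of −0.10 (95% bootstrap interval −0.23 to 0.00157). It cannot be told apart from no enrichment, because transcripts with few reads may need a higher fold to be called, which was not analysed here. More m1G in the transcripts of these lists stays open, untested here.

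Genes of chromosomes 16, 17, 19 and 22 had MetDiff peaks more often. Shorter gene spans on these chromosomes were examined as a cause. Within 4 strata of gene span the odds ratio against other chromosomes stayed between 1.56 and 2.17, with Fisher's exact p of at most 4.08e-09. The 4 chromosomes were grouped after their shares, the highest, were seen. An excess over all genes was thus fixed in advance, and the p-values are no test of it. The shortest stratum had the lowest share with a peak, 19.9% on these chromosomes and 10.8% elsewhere. In the longer strata, from short to long, it was 27.2%, 33.6% and 29.1% on these chromosomes and 19.3%, 18.9% and 16.3% elsewhere. These values argue against span as the whole cause. GC content, which is high on these chromosomes, expression level and guanine content of the transcripts stay open and were not analysed here. No biological explanation was tested.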
